A study of Homo sapiens with 2 samples.

How the data were processed

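Total RNA from UACC62 cells, an established human melanoma line, was measured on 2 whole-transcript arrays. Per the labels' protocols, 1 culture had received a non-targeting siRNA and 1 an siRNA against FOSL1, and both were harvested on day 3 after transfection. Whether the siRNA was a single sequence or a pool was not given in the sources used here, so off-target effects of the siRNA cannot be separated from those of FOSL1 depletion in any difference. RNA was purified on columns, 100 ng was amplified with a whole-transcript kit, and single-stranded DNA was labelled with biotin and hybridised to an Affymetrix array, per the labels. Each condition was therefore represented by 1 array, and the number of arrays limits the precision of every value.

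The deposited values were 1 number per probe set and array, taken here as log2 intensities after their range, which ran from 2.226 to 14.81 over 53427 probe sets. The log base, the background correction, the method that combined probes into probe sets, and any genome build behind the array design were not given in the sources used here. Both arrays had a median of 6.885, and when each array was sorted the values at the same rank differed by at most 0.0301. The arrays thus had almost the same distribution in the deposited values, as quantile normalization leaves it, although the step that made it so is not stated in the labels. A shift in the total RNA per cell could not be seen on such a scale. Scanner intensities were not used here.

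Genes were named from the table of probe set names used here, which gave 1 gene symbol to 16098 probe sets and several symbols to 0. It did not name the other 37329 probe sets (69.9%), which were kept out of the gene results and counted by themselves. The 14884 genes were matched by Entrez ID to the RefSeq gene table of assembly GRCh38.p14, where all 14884 were found and 0 symbols differed. Of these genes, 779 had several probe sets, and the probe set with the highest mean over both arrays stood for the gene. Genes with a mean log2 value at or above the median of named genes, 8.021, passed the filter on dim genes, which left 7442.

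The measure was the log2 value with FOSL1 siRNA minus the log2 value with control siRNA, so that negative values were lower with FOSL1 siRNA. With 1 array per condition no test was run and no p-value or replicate error could be given. Genes at least 2-fold higher or lower were counted as a description of size. Among 213 genes with at least 2 probe sets past the filter, the differences measured by the 2 brightest probe sets lay a median of 0.082 log2 units apart and had a Pearson correlation of 0.436 across genes, which are not independent replicates. The corresponding SD between probe sets of a gene was 0.169. This spread arises within 1 pair of arrays and leaves out any variation between cultures.

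Before the data were examined, 22 gene lists were fixed. They covered the AP-1 family, described FOSL1 or AP-1 targets, melanocyte lineage and pigmentation, dedifferentiated or invasive melanoma, epithelial-mesenchymal transition, ERK pathway output, mitosis, DNA replication and S phase, p53 targets and cell cycle inhibitors, and the type I interferon response. The others were NF-kB cytokines and chemokines, cholesterol synthesis, the unfolded protein and ATF4 response, hypoxia and glycolysis, TGF-beta and YAP targets, integrins with matrix and focal adhesion genes, neural crest and neural genes, apoptosis regulators, RNA interference machinery, housekeeping genes, markers of keratinocytes and other epithelia, and markers of fibroblasts, endothelium and leukocytes. The lists were written from general knowledge, and some genes stood in several of them. For each list, the median difference of the members that passed the filter was placed among the medians of 10000 random lists of the same size, drawn within 20 bins of mean log2 value with a fixed seed. A list below percentile 2.5 or above percentile 97.5 was said to stand apart, which describes these 2 arrays and is not a test of the treatment.

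The rule for named genes was also fixed before the data were examined. It took FOSL1, the 15 characterised genes with the largest positive and the 15 with the largest negative difference among genes that passed the filter, and every AP-1 family member that passed it. From each list it took up to 2 members per direction that differed by at least 1.5-fold, or the 1 with the largest difference where none did. Pseudogenes, small RNAs, uncharacterised genes and sex-linked marker genes were excluded by this rule. Genes named outside it were chosen after their values were seen, and the text says so where they appear.

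The alternatives were centring each array on its median, quantile normalization over the named genes, removal of a loess trend on mean log2 value, no filter on dim genes, a filter at the 75th percentile, the mean of all probe sets of a gene, thresholds of 1.5-fold and 3-fold, list means in place of medians, and lists without members shared with another list. A change of pseudocount was not run, because the values were already logarithms. Alternatives chosen after seeing the data were random lists matched on gene span as well as mean value (10 bins each), removal of a loess trend on gene span, and a count of probe sets without a gene name. Gene span was the length from the start to the end of the gene in the RefSeq table. As no build is stated for the array, it was used only as an approximate property of each gene, matched by Entrez ID, and no coordinates are given.

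The calculations were tested on simulated data for 7442 genes, each drawn independently from a normal distribution with the spread seen between these 2 arrays. Variation between cultures and genes that vary together were left out, so the results check the code and not the error rate of the comparison. With a log2 change of 1.5 added to 200 genes, 199 were recovered past the 2-fold threshold in the right direction. None of the genes left alone passed that threshold, which lies far outside the simulated spread. Of 100 random lists of 20 genes with no shift, 4 fell outside the central 95% of matched random lists, and 94 of 100 lists shifted by 0.2 log2 units lay above percentile 97.5. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.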

Results

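Gene expression was measured in UACC62 human melanoma cells 3 days after transfection with a non-targeting siRNA (1 array) or with an siRNA against FOSL1 (1 array). FOSL1, also called FRA1, is a member of the FOS family that pairs with JUN proteins to form the transcription factor AP-1. The series title places the experiment in a study of how FOSL1 acts in the reprogramming and transformation of melanocytes, and the comparison asks which transcripts differ when FOSL1 is depleted in a melanoma line. Of 14884 named genes, 7442 passed the filter on dim genes. Across all probe sets, named or not, the 2 arrays had a Pearson correlation of 0.9874. There was no replicate of either condition, so none of the differences had a replicate check, and they describe these 2 arrays.

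FOSL1 itself (Entrez gene 8061, probe set 16740630) had a log2 value of 11.90 with control siRNA and 10.38 with FOSL1 siRNA. This log2 difference of -1.53, a level 2.88-fold lower, was the lowest of the 7442 genes, and the targeted gene thus differed in the direction the labels give.

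Few other named genes differed by as much. In the array with FOSL1 siRNA, 6 of the 7442 genes were at least 2-fold higher and 3 were at least 2-fold lower. Of these genes, 98.1% lay within 1.5-fold. Probe sets without a gene name are left out of these counts. Of the 8244 at least as bright as the filter, 58 were at least 2-fold higher and 23 at least 2-fold lower. PTGS2, the inducible cyclooxygenase COX-2 that makes prostaglandin precursors, had the highest log2 difference, 1.32, with log2 values of 10.90 in the control array and 12.22 with FOSL1 siRNA. LRRC17, a secreted leucine-rich repeat protein, was 2.33-fold higher, PCDH18, a protocadherin of the cell surface, 2.17-fold, and CFI, the protease complement factor I, 2.13-fold. PLSCR4, of the phospholipid scramblase family, was 2.09-fold higher and IFIT3, an interferon-induced gene, 2.02-fold. Next to FOSL1, UCN2 had the lowest difference. UCN2, which encodes the peptide hormone urocortin 2, was 2.10-fold lower (log2 values of 11.94 and 10.87), but its difference was -0.98, under 2-fold, when a trend on gene span was removed. The remaining gene at least 2-fold lower was the pseudogene RPL23AP82, named here after its values were seen. Its brightest probe set differed by -1.02, but its other probe sets, which share the same values, differed by 0.35 in the opposite direction. CFI and IFIT3 lay near the filter on dim genes, with control log2 values of 7.82 and 7.67.

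**Figure D1:**
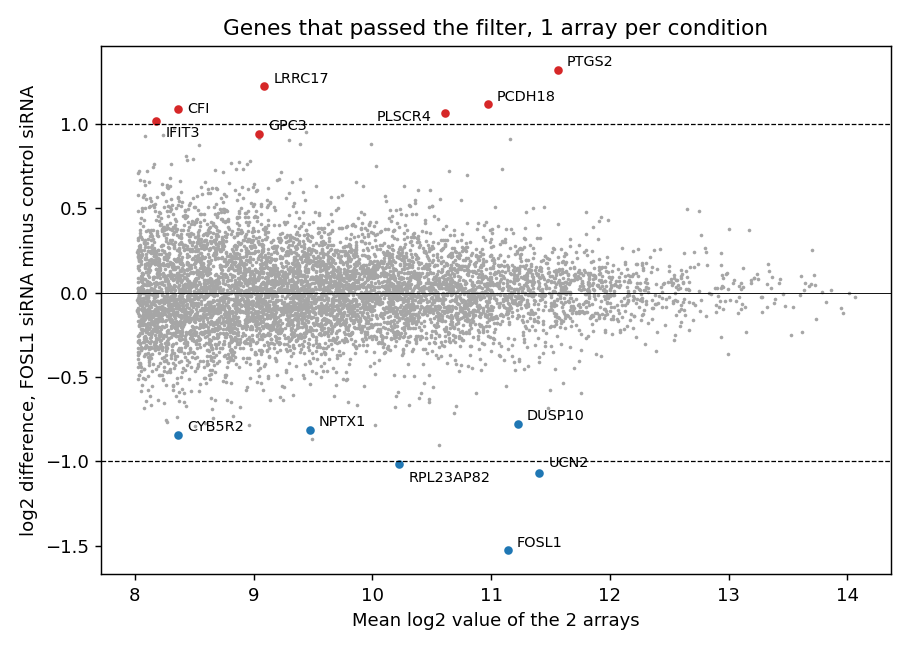
Each point is 1 of the 7442 genes that passed the filter, with the mean log2 value of the 2 arrays on the horizontal axis and the log2 difference, FOSL1 siRNA minus control siRNA, on the vertical axis. Dashed lines mark 2-fold differences, named genes are coloured, and FOSL1 is the lowest point at -1.53 while PTGS2 is the highest at 1.32.

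At a threshold of 1.5-fold, 84 genes were higher and 57 were lower. Of these, 20 lower and 4 higher genes had the symbol stem MIR of microRNA genes. That stem was examined after the values were seen, and the rule for named genes left out small RNAs. DUSP10, a phosphatase that inactivates the stress kinases p38 and JNK, was 1.72-fold lower (log2 values of 11.61 and 10.83), and VGF, the precursor of several neuropeptides, was 1.58-fold lower. NPTX1, a secreted neuronal pentraxin, was 1.76-fold lower, and the long non-coding RNA LINC00520 was 1.72-fold lower. The metabolic genes CYB5R2, a cytochrome b5 reductase, and GPAT3, which starts glycerolipid synthesis, were 1.79-fold and 1.60-fold lower. SMAGP and RELL1, both membrane proteins, were 1.61-fold and 1.59-fold lower at high log2 values of 11.82 and 11.04 in the control array. The other genes among the 15 with the largest negative differences were COLQ, KRTAP10-9, AHNAK2, CD209 and TM6SF2, with log2 differences between -0.74 and -0.66. With FOSL1 siRNA, the log2 values of CYB5R2, COLQ, CD209 and TM6SF2 were 7.94, 7.98, 7.74 and 7.80, under the filter on dim genes.

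Among the higher genes, GPC3, a glypican proteoglycan of the cell surface, was 1.92-fold higher and CD82, a tetraspanin, was 1.90-fold higher. RGS5, a regulator of G protein signalling, was 1.83-fold higher and CACHD1, a protein related to calcium channel subunits, 1.88-fold, the latter at a log2 value of 11.61 with FOSL1 siRNA. OXR1, named for its role in resistance to oxidative damage, was 1.88-fold higher by its brightest probe set, with a log2 difference of 0.91, and its dimmer probe set gave 0.49. GIN1, CCDC102B and GEMIN8 had log2 differences of 0.93, 0.97 and 0.81. In the control array the log2 values of CD82, GIN1 and CCDC102B were 7.62, 7.77 and 7.84, under the filter on dim genes. RGPD4 had a difference of 0.92, but it belongs to a family of near-identical genes and its value is uncertain.

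Other AP-1 subunits differed less than FOSL1. Of the 13 family members that passed the filter, 10 were below 0 and 3 above, and none differed by 1.5-fold. JUN, the main partner of FOS proteins, had a log2 difference of -0.48 and JDP2, a JUN-binding repressor, -0.44. JUND and FOSB differed by -0.29 and -0.22 and JUNB by -0.13, although the dimmer probe set of FOSB gave 0.08. FOS and FOSL2, of the same family as FOSL1, both had differences of -0.04. MAFF and ATF2 had differences of -0.07 and -0.06, while NRL, MAF and MAFG had 0.02, 0.05 and 0.09. ATF4 was at -0.00, which gives it no direction, and FOS was at 0.05 when a trend on gene span was removed. The family median of -0.06 lay at percentile 20.8 of the matched random lists, whereas the family mean of -0.13 lay at percentile 2.23, outside the central range. Against random lists matched on gene span as well, the family median lay at percentile 40.3. The family mean was not compared with lists matched on span.

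Genes described as targets of FOSL1 or AP-1 stood apart toward lower values. The median of the 17 that passed the filter was -0.12, at percentile 1.12 of random lists matched on mean log2 value, and 11 of them were below 0. MMP1, the interstitial collagenase, was 1.55-fold lower and LIF, a cytokine of the interleukin 6 family, 1.47-fold lower. HMGA1, a chromatin protein chosen after its values were seen, had differences of -0.59 and -0.45 on its 2 probe sets. Members also lay on the other side: CCL2, a chemokine that attracts monocytes, was 1.57-fold higher, and AXL, a receptor tyrosine kinase, had a log2 difference of 0.41. Short genes tended to have lower differences than long genes, and when the random lists were matched on gene span as well, the percentile of this list was 4.64 and it no longer stood apart. The same held with no filter on dim genes, at percentile 5.51, and for the mean of the list, at 3.39.

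Mitosis genes stood apart toward higher values, although no member reached 1.5-fold. All 27 named members passed the filter, 20 were above 0, and the median of 0.14 lay at percentile 99.96. The largest difference was 0.41 for NDC80, a kinetochore protein. MKI67 (0.32), the proliferation marker Ki-67, and PLK1 (-0.25), a mitotic kinase, were named after their values were seen and show that members lay on both sides. DNA replication and S phase genes had a median of 0.03 at percentile 76.6, with 18 of 29 above 0, and CLSPN, a replication checkpoint mediator, had the largest difference at 0.36. The list of p53 targets and cell cycle inhibitors had a median of 0.14 at percentile 97.8, just outside the central range, with 8 of 13 members above 0, and its mean of 0.12 lay at percentile 96.05, inside that range. This list held 28 genes, of which 14 had a named probe set here, without MDM2, CDKN1A or any other listed CDKN inhibitor. Its largest difference was that of TP53INP1, a p53-induced stress gene, which was 1.69-fold higher. BAX, a p53 target that promotes apoptosis, was on the other side with a difference of -0.27 and was named after its values were seen. Of the 21 lists that had a median, these 3 stood apart, where chance alone would put 1.05 outside the central range. That figure takes genes and lists as independent, whereas some lists share members and genes of 1 process can vary together. When the random lists were matched on gene span as well, 2 lists lay outside.

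**Figure D2:**
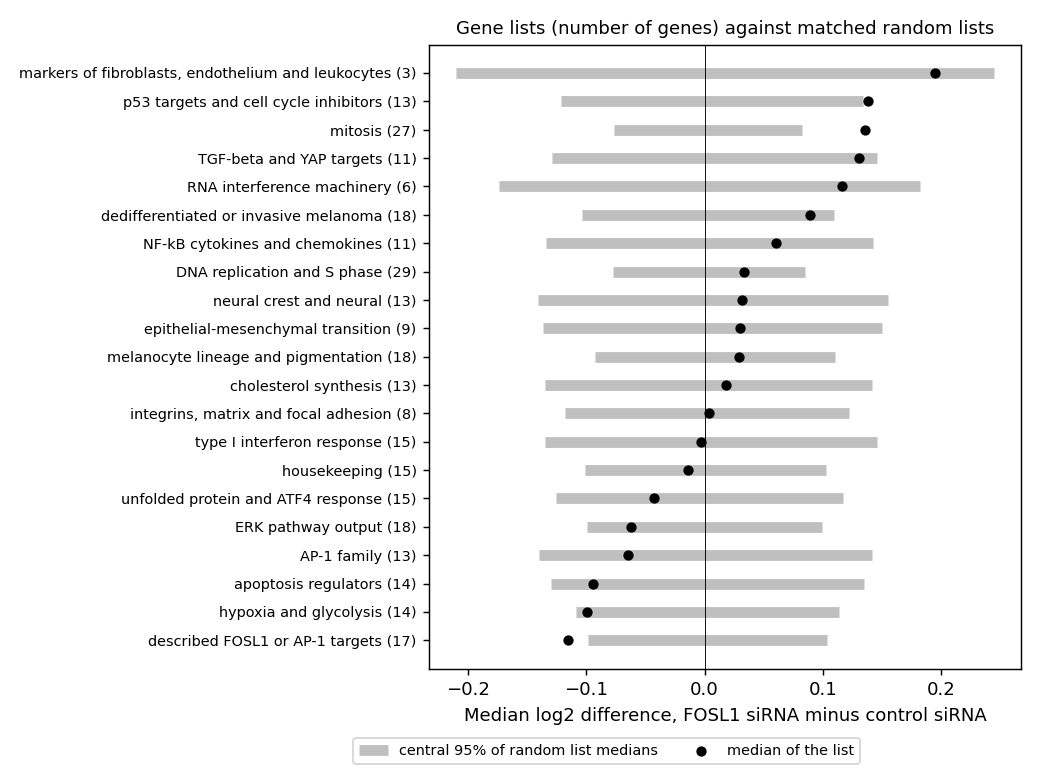
Each dot is the median log2 difference, FOSL1 siRNA minus control siRNA, of a gene list, with the number of members that passed the filter in brackets, and each grey bar spans the central 95% of the medians of 10000 random lists matched on mean log2 value. The mitosis list at 0.14 and the p53 list at 0.14 lie beyond the upper end of their bars and the FOSL1 or AP-1 targets at -0.12 beyond the lower end.

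Genes of melanocyte identity lay on both sides of 0. The 18 lineage and pigmentation genes that passed the filter had a median of 0.03 at percentile 65.4, with 10 above 0 and none past 1.5-fold. MLPH, which links melanosomes to their motor, had the largest difference at -0.41. The central regulators were chosen after their values were seen: MITF, the master transcription factor of melanocytes, had a log2 difference of 0.36, whereas SOX10, which acts upstream of it, had -0.30 and TYR, the rate-limiting enzyme of melanin synthesis, -0.34. Genes of dedifferentiated or invasive melanoma had a median of 0.09 at percentile 94.8, with 12 of 18 above 0, and LPAR1, a receptor for lysophosphatidic acid, led with 0.49. This list stood apart as a mean (percentile 98.11), after quantile normalization over the named genes (98.48) and after removal of the span trend (98.75), but lay at percentile 86.7 among random lists matched on span. Neural crest and neural genes had a median of 0.03 at percentile 68.7, and the water channel AQP1 was 1.71-fold higher. The neural list stood apart as a mean of 0.15 (percentile 98.04), without members shared with other lists (98.2) and with the filter at the 75th percentile (99.83). The epithelial-mesenchymal transition list had a median of 0.03 at percentile 63.4, with CLDN1, a tight junction protein, at 0.31. The median of that list was -0.15, at percentile 1.59, when the filter was set at the 75th percentile.

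The medians of the inflammatory and interferon lists lay within the central range. NF-kB cytokines and chemokines had a median of 0.06 at percentile 78.4, with PTGS2 and CCL2 at least 1.5-fold higher and 7 of 11 members above 0. LIF, also on this list, was lower as given above, and CXCL2, a chemokine named after its values were seen, had a difference of -0.39. The mean of this list, 0.16, was at percentile 98.73, and its median with the filter at the 75th percentile was at 99.99, both outside the central range. Interferon response genes had a median of -0.00 at percentile 49.5, with 7 of 15 members above 0 and IFIT3 as the member at least 1.5-fold higher. The mean of the interferon list was 0.09, opposite in sign to a median too close to 0 to have a direction. With no filter on dim genes the median of this list was 0.11 at percentile 99.16.

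The medians of signalling and adhesion lists also lay within the central range. ERK pathway output genes had a median of -0.06 at percentile 11.1, with 11 of 18 below 0 and LIF as the largest difference. TGF-beta and YAP targets had a median of 0.13 at percentile 96.2, with AXL the largest, but without members shared with other lists the median was -0.00. The list of integrins, matrix and focal adhesion had a median of 0.00 at percentile 50.2, with 4 of 8 on each side, and a mean of -0.05. Of its 35 genes 9 had a named probe set here, without any integrin, collagen or laminin, so its values do not cover these. Without members shared with other lists the median was -0.24 at percentile 0.82, outside the central range. The focal adhesion protein ZYX was at -0.42.

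Medians of the stress and metabolic lists were within the central range as well. Hypoxia and glycolysis genes had a median of -0.10 at percentile 3.91, and 11 of 14 were below 0. The mean of -0.14 lay at percentile 0.32 and the median without shared members, -0.17, at 0.75, both outside the central range. PGAM1, a glycolytic mutase, was 1.57-fold lower. Apoptosis regulators had a median of -0.09 at percentile 8.21, while BCL2, which blocks apoptosis, was at 0.37. The median was -0.0072 at percentile 47.9 without members shared with other lists, and -0.0281 at percentile 26.0 with the span trend removed. The unfolded protein and ATF4 response list had a median of -0.04 at percentile 27.6, and DDIT3, the stress transcription factor CHOP, was at 0.51. Cholesterol synthesis genes had a median of 0.02 at percentile 62.6, and STARD4, a sterol carrier, was at 0.58.

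Of the lists included as controls, none that had a median stood apart with the filter on dim genes. The interferon list above was also fixed as a transfection control, and with no filter it stood apart at percentile 99.16. Housekeeping genes had a median of -0.01 at percentile 34.9, and the largest difference was 0.50 for VPS29, a retromer subunit. The 6 genes of the RNA interference machinery had a median of 0.12 at percentile 89.2, with TARBP2, a partner of Dicer, at -0.32. None of the 16 named markers of keratinocytes and other epithelia passed the filter, and their highest mean log2 value was 7.84. Of the markers of fibroblasts, endothelium and leukocytes, 3 passed it, with a median of 0.19 at percentile 94.8, and CD68, a lysosomal protein of macrophages, was 1.55-fold lower. The median of the 10 named members of this list with no filter was on the other side of 0, at -0.17 and percentile 4.36, and the mean of the 3 was 0.0154 at percentile 52.2.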

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

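The array also carries probe sets without a name in the table used here, and these were examined only after the named genes had been seen. Probe set 16889733 had a log2 value of 8.31 with control siRNA and 10.82 with FOSL1 siRNA, a difference of 2.51, and probe set 16975298 had 8.48 and 10.84, a difference of 2.36. Both differences exceed the highest of any named gene that passed the filter, 1.32 for PTGS2, and they lie in data outside the gene comparison. In the other direction, probe set 17118415 had 9.80 and 7.95, a difference of -1.85, which is lower than the -1.53 of FOSL1. In all, 8244 unnamed probe sets were at least as bright as the filter on named genes, and of these 58 were at least 2-fold higher and 23 at least 2-fold lower. Some carry copies of the same measurement, and counting each pair of values once gave 57 and 21. The genes behind these probe sets were not analysed here, and no explanation for their values was tested.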

How the results depend on the processing

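Alternatives on gene span and the count of unnamed probe sets were chosen after seeing the data and the others before. FOSL1 lay between -1.54 and -1.45 under the 4 alternatives that could change its value, and ranked 2 from the lowest with no filter. The counts of genes at least 2-fold higher and lower were 38 and 13 with no filter, since dim genes entered, while 3 were higher at the 75th percentile filter. They were 8 and 2 with the span trend removed, 6 and 2 as a mean of probe sets, 84 and 57 at 1.5-fold and 0 and 0 at 3-fold. For other named genes, 246 values under alternatives that altered them moved by less than the SD between probe sets and 1 by more (OXR1, 0.70 as a mean of probe sets), while 139 were unaltered by construction. The arrays had almost the same distribution, so scaling could move these values little. A mean of probe sets alters only genes with several, so these counts are no sign that the differences would repeat. The mitosis list stayed between percentiles 99.87 and 100.0, the p53 list between 96.05 and 99.71, and the FOSL1 or AP-1 targets between 0.09 and 5.51. The p53 list no longer stood apart as a mean, nor did the targets as a mean or with no filter.

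List medians that moved by more than the SD of random medians were as follows, and the cause was not tested. With no filter they were interferon 0.108, integrins -0.0716 and fibroblast, endothelium and leukocyte markers -0.17. At the 75th percentile they were epithelial-mesenchymal transition -0.15, NF-kB 0.33, cholesterol -0.0685, TGF-beta and YAP -0.0049, integrins 0.0797 and neural 0.31. Without shared members they were FOSL1 or AP-1 targets -0.18, p53 0.20, hypoxia -0.17, TGF-beta and YAP -0.0049, integrins -0.24, neural 0.19 and apoptosis -0.0072. As means they were interferon 0.0904, NF-kB 0.16, neural 0.15 and fibroblast, endothelium and leukocyte markers 0.0154. With the span trend removed they were interferon 0.0884, unfolded protein 0.033 and neural 0.12. Of the other values of lists, counts and FOSL1, 142 moved by less than their limits and 42 did not move. Among the named genes at least 1.5-fold different and the lists that stood apart, none changed direction. For those genes the scaling alternatives shifted values too little for a change of direction.

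No paired analysis was possible because each condition had 1 array, and for the same reason leaving out an array was not run. The pseudocount was not run because the values were already logarithms. Dim genes limit the counts: of the 7442 genes below the filter, 32 were at least 2-fold higher and 10 lower.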

Other observations

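Gene families that share a symbol stem were examined after the values were seen. Of 77 families with at least 10 genes past the filter, 9 lay outside the central range of matched random lists. Chance would put 3.85 there if genes were independent, but members of a family can vary together. Zinc finger genes of the ZNF series, many of them transcriptional repressors, had a median log2 difference of 0.09 over 248 genes, at percentile 100 also when random lists were matched on gene span. The 12 clustered protocadherins of the PCDHB series, adhesion proteins of the cell surface, had a median of 0.22, at percentile 99.95 and at 100 when matched on span. All 12 were above 0, but their sequences are similar and their probe sets are not independent measurements. MicroRNA host and precursor genes had a median of -0.26 over 163 genes past the filter, 130 of them below 0. The 935 microRNA genes under the filter had a median of -0.09. Keratin-associated protein genes, hair structural genes of the KRTAP series, had a median of -0.30 with 13 of 13 below 0. The 72 under the filter had a median of -0.13, while the 13 lay at percentile 0, or 1.60 when matched on span. The others outside were USP (percentile 99.92), CEP (99.85), SEC (99.5) and KIF genes (97.6) toward higher values and MYO genes (1.91) toward lower ones, and KIF was inside the range at 90.0 when matched on span. With span matching 10 families lay outside, among them HDAC (1.87) and RNF genes (1.72) toward lower values, which had been inside at 7.40 and 3.79. The median of each of these families kept its sign under the 3 scaling alternatives. These shifted the medians too little to change a sign, so the check decides nothing.

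In the tests that follow, those of RNA quality and of the interferon response were chosen only after the result was seen, while the others were written before their values were computed but after the overall span trend and the genes had been seen.

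The log2 difference was higher in genes with a longer span. Across 6928 protein-coding genes past the filter Spearman's rho was 0.34 (bootstrap interval over genes 0.32 to 0.36), and genes are not independent replicates; of 5 equal groups by span, the shortest had a median of -0.11 and the longest of 0.09. A labelling or hybridisation bias acting on all probe sets would give a trend above 0.1 also in the dimmest of 4 equal groups, by mean value, of all named protein-coding genes with no filter, and rho there was 0.0705 with an interval of 0.0348 to 0.1032, which does not decide it. A response of transcribed genes predicts a stronger trend in bright genes, and rho was higher by 0.2655 (0.2156 to 0.3117) in the brightest of the 4 groups than in the dimmest. A difference in RNA quality or amplification predicts the same, and with rho of 0.336 in the brightest group and 1 array per condition it cannot be told apart from a response to the siRNA.

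The lists that stood apart could reflect this span trend. Against random lists matched on span as well, the mitosis list lay at percentile 99.98 and the p53 list at 99.65. Their random medians were -0.0072 and -0.0374 with span matching, under the 0.0034 and 0.0019 without it. The spans of these lists would thus lower them, so the trend did not account for their higher medians. As matching moved the random medians down, the percentiles it gave are no further evidence for either list. The FOSL1 or AP-1 targets lay at 4.64, inside the central range, as the trend predicts, but at 2.14 after the trend itself was removed, so part of their shift may be separate. A link between FOSL1 depletion and the higher median of the mitosis list, 7 of whose 27 members were below 0, remains a hypothesis from 1 array per condition. Off-target effects of the siRNA or differences in cell density or transfection between the cultures were not tested.

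PTGS2, CXCL8 (0.58, a chemokine), CCL2 and IFIT3 were picked out after their values were seen, and CXCL2 and LIF of the same NF-kB list had differences of -0.39 and -0.56. After removal of the span trend the first 3 had a median of 0.7461, but these are short genes that the trend lowers, so its removal could only raise them and the test decides nothing. An interferon response as large as that of IFIT3 would raise many of the 27 other interferon genes by 1.5-fold, and 0 were, counted without a filter. This test replaced earlier forms, which used the 14 others past the filter (0 at least 1.5-fold higher) and the percentile of the unfiltered median of the 27, 97.23, just inside the central range. A weaker interferon shift stays open, since the whole list without a filter lay at percentile 99.16. Among the 27 others, 14 were above 0, and IFI44 (0.58) and IFIT2 (0.52) lay close under the 1.5-fold limit. Both are dim genes named here after their values were seen, so the count of 0 depends in part on where that limit falls.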
